A study of Homo sapiens with 3 samples.

How the data were processed

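RNA was measured by sequencing in MJ cells, an established cutaneous T cell lymphoma line, after stable lentiviral transduction with a scrambled short hairpin RNA (shRNA) or with 1 of 2 hairpins against SATB1. Each of the 3 groups has 1 library. The hairpin sequences, the read length, the strand setting of the library kit and the time between transduction and harvest are not given in the sources used here. Per the labels' protocols, total RNA was extracted, treated with DNase and made into libraries by standard Illumina methods.

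The deposited values are FPKM, fragments per kilobase of gene scaled to library size, per the file headers. The submitters' processing notes name bcl2fastq 2.19.0.316, HISAT2 2.0.4, StringTie, edgeR and the genome build hg38, without saying what each was used for. The annotation, the gene lengths and how the library-size total was set are not given in the sources used here. No count table was used, so depth was read from low values. In single-exon genes the most common low value of FPKM times gene length was taken as the worth of 1 counted fragment. Of the values up to 20 fragments, 99.2%, 99.3% and 99.3% in the scrambled, shRNA 1 and shRNA 2 libraries fell within 2% of a whole number of fragments. These steps give library-size totals of 16.4 M, 14.2 M and 13.9 M fragments. In multi-exon genes 40.9%, 42.3% and 42.1% of such values were whole. The reason was not tested, and fragments per gene are therefore estimates and no count test was run. The median expressed gene had an estimated 400.0 fragments in the scrambled library and the 10th percentile gene had 70.0. Intervals on FPKM ratios are exact Clopper-Pearson 95% intervals from these estimated fragments. They cover counting error only, not differences between cultures or libraries.

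Gene symbols, types and coordinates came from GENCODE release 29 on GRCh38. Of 50868 Ensembl identifiers in each table, 50111 matched it and 757 did not. All columns of values were mapped to a sample. Values were analysed as log2(FPKM + 1), on which the fold change of a low gene is understated. Genes with a mean of at least 1 FPKM over the 3 libraries were called expressed, 10506 in all, of which 10474 had a symbol and 9163 were protein-coding. With 1 library per group no p-value was computed for a single hairpin. Genes were counted when they were at least 2-fold apart, with shRNA 1 against scrambled, with shRNA 2 against scrambled, with both hairpins in the same direction, and between the hairpins. Both hairpins share the scrambled library, so 100 sets of 3 unchanged libraries were simulated with the spread seen between the hairpin libraries in 20 bins of mean expression, and the simulated counts stand beside the observed ones. The scrambled library cannot be split, so part of any excess over independent lists may come from it.

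A secondary fit compared both hairpins as 1 arm of 2 libraries with the scrambled library by limma-trend with robust empirical Bayes moderation and Benjamini-Hochberg adjustment, with an adjusted p under 0.05 as the threshold. It has 1 residual degree of freedom, from the hairpin libraries, and the lone scrambled library is assumed to vary as they do. Its p-values measure only the spread between these libraries. On 20 simulated data sets of 10506 genes with 200 changed, well expressed genes, this fit recovered 24.8% of genes changed 2-fold and 98.4% of genes changed 8-fold. On average 17.2 unchanged genes were called, or 12.3% of all calls, so its adjusted p-values were too small in this simulation. Each simulated library drew its deviations from all genes of similar expression, so a gene's own spread was not kept. No paired fit or leave-one-out was possible with 1 library per group.

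31 gene lists were fixed before the data were examined, covering the cell cycle, p53 targets, apoptosis, T helper and regulatory T cell genes, T cell receptor signalling, T lineage transcription factors, cutaneous T cell lymphoma genes, NF-kB targets, interferon response, MHC, cytokine receptors, chemokines, metabolism, stress responses, chromatin architecture, ribosomal and mitochondrial genes, and markers of other cell types. For lists with at least 3 expressed members, 27 in all, the median log2 fold change was placed among 10000 random lists of the same size matched on mean expression. This percentile describes these libraries, and because random lists treat genes as independent, list medians between the hairpin libraries are given as a yardstick. Members passing limma were counted over all genes and adjusted over the list alone.

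The named genes were also chosen by a rule set before the data were examined. They are SATB1, the 12 genes with a symbol that were highest and the 12 lowest by the smaller of their changes among those at least 2-fold changed with both hairpins, up to 6 members of each list that were at least 2-fold changed with both, and up to 3 genes past 2-fold in opposite directions. 1 gene that the rule names is not reported here. Genes named outside the rule are said to be so where they appear. For each gene the share of its transcript 31-mers that also occur in another gene was computed from 1 in 16 sampled 31-mers of the GENCODE transcripts, since reads there could be assigned to either gene. Alternatives tried were a pseudocount of 0.1, centring on the median fold change, no filter, a mean of at least 5 FPKM, a 1.5-fold threshold, limma without trend or robust moderation, and an adjusted p under 0.1. A count without genes that share at least 50% of their 31-mers, pseudogenes and identifiers without a symbol was added after seeing the data. Alternatives fixed for count tables did not apply to FPKM. Computation used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and R 4.3.3 with limma 3.58.1.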

Results

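Gene expression was measured in 3 libraries of MJ cells, a T cell line established from cutaneous T cell lymphoma. 1 library came from cells with a scrambled shRNA, 1 from cells with SATB1 shRNA 1 and 1 from cells with SATB1 shRNA 2. The design asks which genes depend on SATB1, a DNA-binding chromatin organiser abundant in T cells. With 1 library per group, differences between a hairpin and the scrambled library have no replicate check. FPKM values were above 0 for 20528 genes in the scrambled library, 20023 with shRNA 1 and 20249 with shRNA 2. The estimated depths were 16.4 M, 14.2 M and 13.9 M fragments. Across expressed genes, which are not independent replicates, Pearson's r of log2 values was 0.978 between scrambled and shRNA 1, 0.980 between scrambled and shRNA 2, and 0.982 between the hairpins.

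SATB1 itself was lower with both hairpins. Its level was 12.1 FPKM in the scrambled library, 7.46 FPKM with shRNA 1 and 8.57 FPKM with shRNA 2. The ratio to scrambled was 0.616 with shRNA 1 (95% counting interval 0.577 to 0.657) and 0.708 with shRNA 2 (0.665 to 0.753), or log2 fold changes of -0.63 and -0.45. SATB1 (ENSG00000182568) lies on the minus strand of chromosome 3 at 18345387 to 18445588 of GRCh38. Of the 10506 expressed genes, 149 including SATB1 were at least as low as it with both hairpins, or 1.42%.

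The genes lowest with both hairpins that have mostly their own sequence included the cytokine genes IL9, OSM and LIF. IL9, a cytokine of type 2 and Th9 cells at 135892246 to 135895827 on chromosome 5, was 55.7 FPKM in the scrambled library, 9.75 FPKM with shRNA 1 and 11.2 FPKM with shRNA 2. Its ratios were 0.175 (95% counting interval 0.137 to 0.221) and 0.201 (0.159 to 0.251). OSM and LIF, cytokines that signal through gp130 and neighbours on chromosome 22 between 30240447 and 30266840, were 20.6 and 24.3 FPKM in the scrambled library. OSM was 3.50 FPKM with shRNA 1 and 4.03 FPKM with shRNA 2, and LIF was 4.98 and 6.32 FPKM. SOCS3, a feedback inhibitor of such cytokine signals, went from 16.2 FPKM to 3.70 and 4.92 FPKM. Besides IL9 and SOCS3, the members of fixed lists at least 2-fold lower with both hairpins were IL5, CCL17, LTA, LTB, BCL6 and IFITM1.

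**Figure D1:**
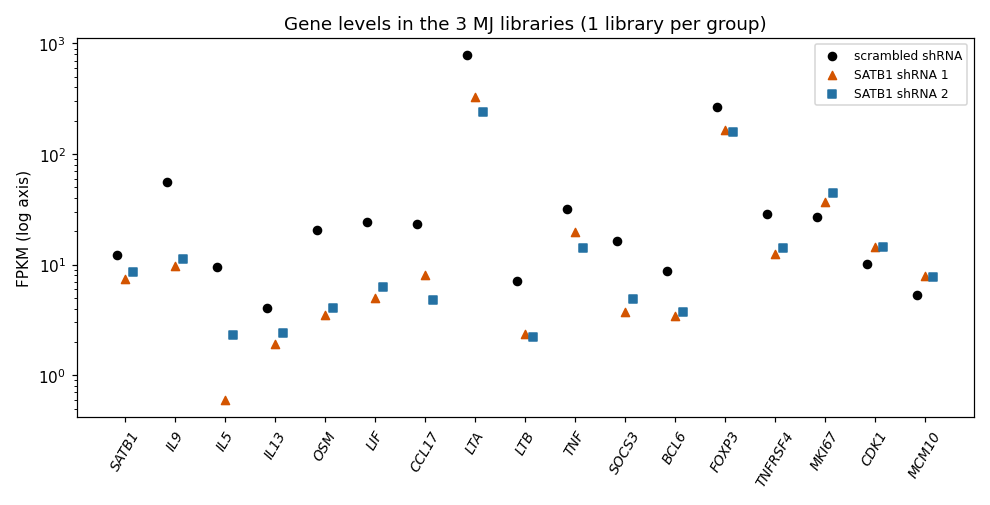
FPKM on a log axis of 17 named genes in the scrambled, SATB1 shRNA 1 and SATB1 shRNA 2 libraries, 1 point per library, with no error bars because each group is 1 library. IL9 lies at 55.7 FPKM in the scrambled library against 9.75 and 11.2 FPKM with the hairpins, a wider gap than that of SATB1 at 12.1 against 7.46 and 8.57 FPKM.

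Th2 genes were lower as a group. Of 12 measured members, 11 were below the scrambled level with both hairpins, and the list medians of -0.47 with shRNA 1 and -0.35 with shRNA 2 were lower than in all 10000 random lists. IL5, the eosinophil growth cytokine, was 9.60 FPKM in the scrambled library, 0.596 FPKM with shRNA 1 and 2.32 FPKM with shRNA 2. The chemokine CCL17 was 23.2, 8.07 and 4.80 FPKM, and IL13 was 4.05, 1.90 and 2.42 FPKM. GATA3, the Th2 master transcription factor, was 89.1, 76.7 and 69.1 FPKM. In limma's fit of both hairpins, no member passed over all genes, and 5, all lower, passed when adjusted over the list alone, namely IL9 (log2 fold change -2.31, SE 0.135, adjusted p = 0.000629), CCL17, IL5, IL13 and IL4R. These p-values take the spread from the hairpin pair and hold no measure of how the single scrambled library would vary, here and for the lists that follow. IL13, GATA3 and IL4R were named after their values were seen, as list members.

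The Th1 and cytotoxic list was lower too, though less evenly. Of its 20 genes 10 were measured, and the granzyme genes, GNLY and NKG7 were under the expression filter. The perforin gene PRF1 had a log2 fold change of -0.08 with both hairpins fitted together. The shift therefore says little about cytotoxic effector genes. The medians over 10 measured members were -0.48 and -0.18, and 7 members were below scrambled with both hairpins. With no expression filter the median with shRNA 1 was -0.18, and with a mean of at least 5 FPKM that with shRNA 2 was -0.35. LTA, which encodes lymphotoxin alpha, was 785 FPKM in the scrambled library, 327 FPKM with shRNA 1 and 240 FPKM with shRNA 2. TNF and TBX21, the latter encoding the Th1 factor T-bet, were 31.7 and 19.7 FPKM in the scrambled library. TNF was 19.6 and 14.0 FPKM with the hairpins and TBX21 was 8.01 and 10.6 FPKM. IFNG split between the hairpins, at 11.1 FPKM in the scrambled library, 3.98 FPKM with shRNA 1 and 14.2 FPKM with shRNA 2. In limma 4 members, all lower, passed when adjusted over the list alone, namely LTA, TBX21, IL12RB1 and TNF, and 0 over all genes. TNF, TBX21, IFNG, IL12RB1 and PRF1 were named after their values were seen.

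Regulatory T cell, NF-kB target and chemokine lists had lower medians with both hairpins. These lists and the Th2 and Th1 lists share some members, so their shifts are not independent. CCL17 is in the Th2, NF-kB target and chemokine lists, and LTA and TNF are in the Th1 and NF-kB target lists. For regulatory T cell genes the medians of 14 members were -0.26 and -0.28, with 10 members below scrambled with both. FOXP3, the lineage factor of regulatory T cells, was 265 FPKM in the scrambled library, 166 FPKM with shRNA 1 and 158 FPKM with shRNA 2. The costimulatory receptor gene TNFRSF4 was 28.9, 12.6 and 14.2 FPKM, and these 2 passed in limma when adjusted over the list alone (adjusted p = 0.0163 and 0.0145), while neither passed over all genes. Both were named after their values were seen. For NF-kB targets the medians of 21 members were -0.25 and -0.33, 14 were below scrambled with both, and 5, all lower, passed when adjusted over the list alone (LTB, LTA, NFKBIA, CCL17 and ICAM1), 0 over all genes. NFKBIA and ICAM1 were named after their values were seen. LTB, next to TNF on chromosome 6, was 7.04 FPKM in the scrambled library, 2.36 FPKM with shRNA 1 and 2.23 FPKM with shRNA 2. For chemokines, chemokine receptors and adhesion genes the medians of 18 members were -0.27 and -0.28, the latter -0.15 with no expression filter, and CCL3 and CCL17, both lower, passed in limma when adjusted over the list alone. CCL3, named after its values were seen, shares 89.7% of its sampled 31-mers with another gene, so its reads could belong to a near-identical copy.

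Cell cycle genes were slightly higher with both hairpins and moved together. All 21 G2/M and mitosis genes were above the scrambled level with both, with medians of 0.34 and 0.43. Of 23 G1/S and DNA replication genes, 22 were above it with both, with medians of 0.37 and 0.31. All 4 medians were higher than in any of 10000 random lists. MKI67, a marker of cycling cells, was 26.8 FPKM in the scrambled library, 37.1 FPKM with shRNA 1 and 44.0 FPKM with shRNA 2. CDK1, the mitotic kinase, was 10.1, 14.4 and 14.3 FPKM, and the replication factor MCM10 was 5.27, 7.85 and 7.67 FPKM. These 3 were named after their values were seen. In limma 0 members of either list passed over all genes or adjusted over the list alone, and 11 of the G1/S and 13 of the G2/M members had an unadjusted p under 0.05.

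**Figure D2:**
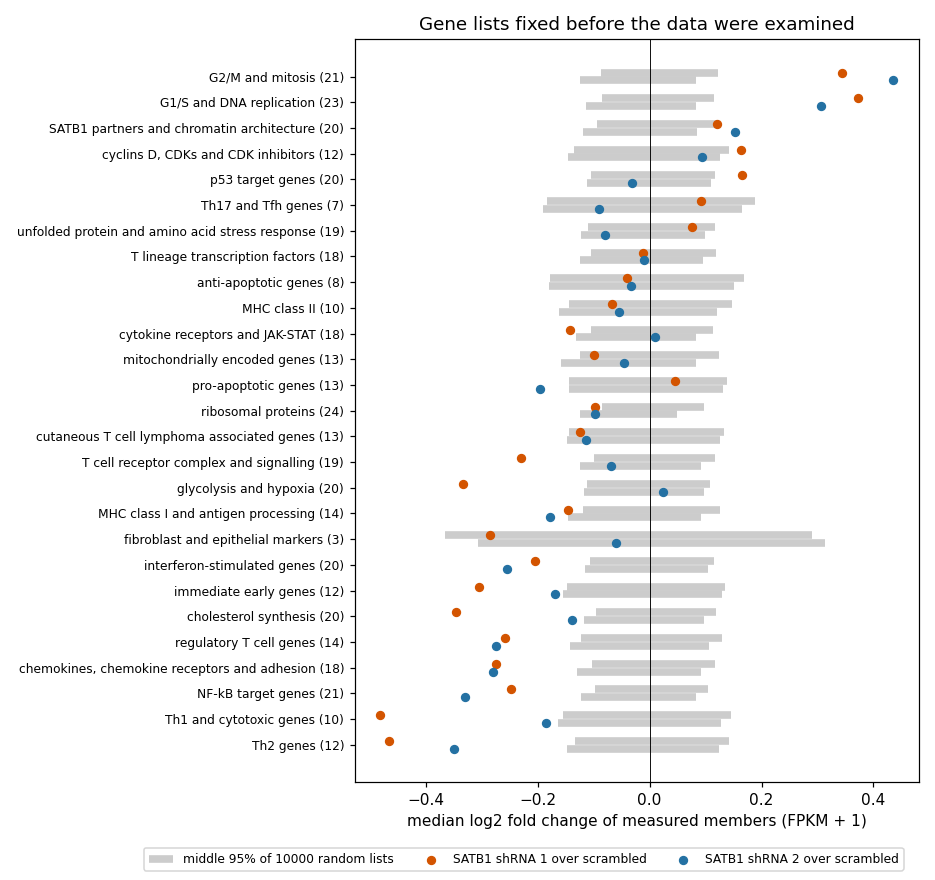
Median log2 fold change of FPKM + 1 for each of 27 gene lists, with the number of measured members in brackets, for SATB1 shRNA 1 and SATB1 shRNA 2 against scrambled. Grey bars span the middle 95% of 10000 random lists matched on size and expression. The 2 cell cycle lists lie to the right of their bars at 0.31 to 0.43 and the Th2 list lies to the left at -0.47 and -0.35.

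In all, 66 genes were at least 2-fold changed with both hairpins, 23 higher and 43 lower. Simulated unchanged libraries sharing a control gave 40.9 on average and 56 at most, with 19.95 higher and 20.99 lower on average, so the observed excess was on the lower side (simulated maximum 36 lower and 32 higher). Independent lists would share 1.16 genes, and part of the excess over that may come from the shared scrambled library. The correlation of the fold changes across genes was 0.590 against a simulated mean of 0.499 and maximum of 0.543, and their covariance was 0.0595 against 0.0414. Of the 66 genes, 24 share at least 50% of their 31-mers with another gene. Without such genes, pseudogenes and identifiers lacking a symbol, there were 42, 15 higher and 27 lower, where simulation gave 35.7 on average and 49 at most. That simulation kept the spread of all genes, including those removed. It gave 96.1 genes at least 2-fold apart between the hairpins on average, against 88 observed. Its range may therefore be too wide, and a count inside it does not decide whether the remaining genes exceed unchanged libraries. In that set the covariance was 0.0477 against a simulated maximum of 0.0479, while the correlation of 0.583 and the 70.3% of genes with the same sign still lay above their simulated maxima of 0.541 and 67.9%.

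The genes highest with both hairpins that have mostly their own sequence included SRP9, GRB2, CS and STARD7. SRP9, a subunit of the signal recognition particle, was 40.6 FPKM in the scrambled library, 129 FPKM with shRNA 1 and 128 FPKM with shRNA 2. GRB2, an adaptor of receptor tyrosine kinase signalling, was 6.74, 24.3 and 19.7 FPKM. CS, the mitochondrial citrate synthase, was 6.94, 19.3 and 19.2 FPKM, and the lipid-transfer gene STARD7 was 10.7, 32.4 and 30.7 FPKM. The proteasome activator PSME3 was 5.02, 17.1 and 13.9 FPKM and the Mediator kinase CDK19 was 1.81, 6.04 and 6.33 FPKM. MRPL34, a mitochondrial ribosomal protein gene, was 1.64, 8.24 and 7.62 FPKM. The antisense gene AC011247.2 was listed at 0 in the scrambled library and at 1.51 and 1.85 FPKM with the hairpins, which rest on an estimated 5 and 6 fragments.

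The largest changes were in genes that overlap others or share sequence with them. The read-through gene BLOC1S5-TXNDC5 was listed at 0 in the scrambled library and at 37.6 and 42.7 FPKM with the hairpins, while TXNDC5, which it contains, was 33.9 FPKM in the scrambled library and 3.35 and 2.82 FPKM with them. BIVM-ERCC5 was 17.6 FPKM in the scrambled library and listed at 0 with both hairpins, while its component ERCC5, named after its values were seen, was 3.68, 9.35 and 10.005 FPKM. AC138811.2, AC007192.1, FRG1KP, AP000275.2 and TNFSF12-TNFSF13 were 7.58, 7.004, 3.93, 3.62 and 3.49 FPKM in the scrambled library and listed at 0 with both hairpins, and each shares at least 90.9% of its 31-mers with another gene. AC012321.1 and AC026464.4 were 6.60 and 5.69 FPKM in the scrambled library and between 0.620 and 1.09 FPKM with the hairpins, and both share 100% of their 31-mers. RHEBP1, AC010422.3 and AC106886.5, higher with both hairpins, share 100%, 92.9% and 91.6%. How reads of such genes were divided cannot be read from FPKM.

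**Figure D3:**
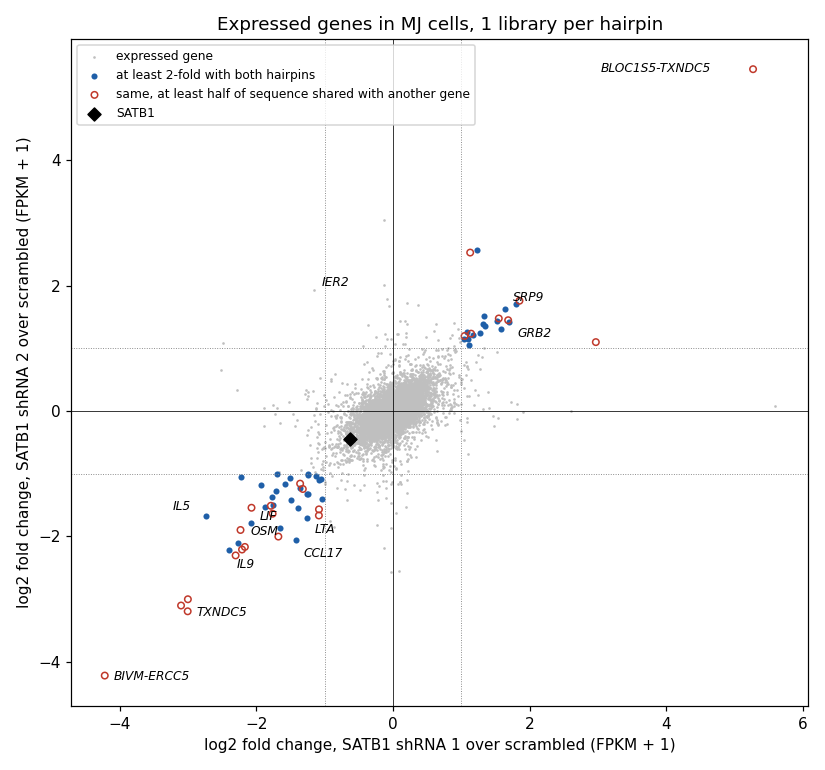
Log2 fold change of FPKM + 1 with SATB1 shRNA 1 (x axis) and SATB1 shRNA 2 (y axis) against the scrambled library, 1 point per expressed gene with a symbol. Dotted lines mark 2-fold, filled points are at least 2-fold changed with both hairpins, and open circles are the 24 of these that share at least 50% of their 31-mers with another gene, which include the extremes BLOC1S5-TXNDC5 and BIVM-ERCC5.

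With each hairpin alone, shRNA 1 left 62 genes at least 2-fold higher and 100 lower than scrambled, and shRNA 2 left 59 higher and 85 lower. Simulated unchanged libraries gave 109.8 and 109.3 genes on average, with maxima of 139 and 132, so both counts lay above the simulated range. Without genes that share sequence they were 119 and 103, within simulated maxima of 122 and 120. Those maxima kept the spread of all genes and may be too high, so this comparison does not decide the matter. Between the hairpins themselves 118 genes were at least 2-fold apart, 52 higher and 66 lower with shRNA 1. Past 2-fold in opposite directions were IER2, an immediate early gene, at 2.36 FPKM in the scrambled library, 0.512 FPKM with shRNA 1 and 11.8 FPKM with shRNA 2, and the read-through gene SENP3-EIF4A1, at 4.59 FPKM, listed at 0, and 10.8 FPKM.

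With both hairpins fitted together against scrambled, limma called 2 genes, BLOC1S5-TXNDC5 higher (adjusted p = 0.0177) and BIVM-ERCC5 lower (adjusted p = 0.0224), the overlapping genes described above. IL9 (adjusted p = 0.0918), OSM and SRP9 (both adjusted p = 0.109) did not pass. SATB1 had a log2 fold change of -0.54 with an SE of 0.139 and an adjusted p of 0.553 in this limma fit. At an unadjusted p under 0.05 there were 842 genes, against 542 and 333 when the shRNA 1 or the shRNA 2 library took the place of the scrambled one.

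Other fixed lists with both medians below the middle 95% of random lists were interferon-stimulated genes (-0.20 and -0.25, 20 members), MHC class I and antigen processing (-0.15 and -0.18, 14 members), cholesterol synthesis (-0.35 and -0.14, 20 members) and immediate early genes (-0.31 and -0.17, 12 members). In limma, adjusted over the list alone, IFITM1, an interferon-induced membrane protein gene, passed in the first of these and SC5D, named after its values were seen, in cholesterol synthesis, both lower, with 0 members of the other 2. With a mean of at least 5 FPKM, the median for cholesterol synthesis with shRNA 2 was -0.08 and that for immediate early genes with shRNA 1 was -0.09. IFITM1 was 28.8 FPKM in the scrambled library, 11.6 FPKM with shRNA 1 and 13.9 FPKM with shRNA 2, with 35.7% of its 31-mers shared. SATB1 partners and chromatin architecture genes lay above it with both (0.12 and 0.15, 20 members). The hairpins parted on glycolysis and hypoxia genes, at -0.33 with shRNA 1 and 0.02 with shRNA 2. Between the hairpin libraries 9 of the 27 lists lay outside the middle 95% of random lists where 1.35 were expected. They included the Th2 list (-0.12), the Th1 and cytotoxic list (-0.13), the G2/M list (-0.07) and cholesterol synthesis (-0.27), as medians of shRNA 1 minus shRNA 2, and the largest median between them was 0.38 in size. That median belongs to glycolysis and hypoxia, and 0 lists moved further than it with both hairpins against scrambled. The G1/S (0.03), NF-kB target (0.05), regulatory T cell (0.07) and chemokine (-0.0029) lists lay inside the middle 95% between the hairpins.

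The remaining lists did not lie outside the middle 95% on the same side with both hairpins. With shRNA 1 alone, medians were outside it for cyclins D, CDKs and CDK inhibitors (0.16, and 0.09 with shRNA 2), p53 targets (0.17, and -0.03), T cell receptor complex and signalling (-0.23, and -0.07), cytokine receptors and JAK-STAT (-0.14, and 0.01) and ribosomal proteins (-0.10, and -0.10). With shRNA 2 alone it was outside for pro-apoptotic genes (-0.20, and 0.05 with shRNA 1), where the median was -0.06 with no expression filter. Within it lay anti-apoptotic genes (-0.04 and -0.03), Th17 and Tfh genes (0.09 and -0.09), T lineage transcription factors (-0.01 and -0.01), cutaneous T cell lymphoma genes (-0.12 and -0.11), MHC class II (-0.07 and -0.06), the unfolded protein and amino acid stress response (0.08 and -0.08) and mitochondrially encoded genes (-0.10 and -0.05). With a mean of at least 5 FPKM, medians moved to -0.18 with shRNA 2 for anti-apoptotic genes, to 0.15 with shRNA 1 for pro-apoptotic genes, to -0.22 with shRNA 2 for cutaneous T cell lymphoma genes, and to -0.09 and 0.09 for T lineage transcription factors. With no filter the cutaneous T cell lymphoma median with shRNA 1 was -0.02. In limma, adjusted over the list alone, PMAIP1, a pro-apoptotic gene named after its values were seen, passed and was higher (49.99 FPKM in the scrambled library, 83.1 and 92.4 FPKM with the hairpins). SOCS3 passed in the cytokine receptor list and BCL6, the follicular helper T cell repressor, in the Th17 and Tfh list, both lower, with BCL6 at 8.72 FPKM in the scrambled library, 3.43 FPKM with shRNA 1 and 3.73 FPKM with shRNA 2. Over all genes, 0 members of these lists passed.

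Markers of other cell types were low in the 3 libraries. The highest value of any B cell marker was 1.94 FPKM, of any myeloid marker 1.91 FPKM, of any NK cell marker 2.63 FPKM, of any fibroblast or epithelial marker 5.09 FPKM and of any red cell marker 0.0286 FPKM. The 3 measured fibroblast and epithelial markers had medians of -0.28 and -0.06, within the middle 95% of random lists, and the former was -0.02 with no filter. The NK receptor gene NCR3, named after its values were seen, was 2.44 FPKM in the scrambled library and 1.06 and 0.911 FPKM with the hairpins. It is 1 of only 2 measured members of the NK cell list, too few for a list median. Mitochondrial genes took 27.0%, 25.6% and 27.0% of all FPKM in the scrambled, shRNA 1 and shRNA 2 libraries.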

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

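The count of splits was the 1 test in this part chosen only after the result was seen. IER2 and SENP3-EIF4A1 drew attention because they moved past 2-fold in opposite directions with the hairpins. Their log2 fold change with shRNA 1 lay below that with shRNA 2 by a difference of -3.08 for IER2 and -3.57 for SENP3-EIF4A1, and the differences were not tested, since each is 1 library against 1. Medians of opposite sign with the hairpins also stood out for 6 gene lists. The difference of the medians, shRNA 1 minus shRNA 2, was 0.20 for p53 targets, 0.24 for pro-apoptotic genes, 0.18 for Th17 and Tfh genes, -0.15 for cytokine receptors and JAK-STAT, -0.36 for glycolysis and hypoxia, and 0.15 for the unfolded protein and amino acid stress response. These differences have no replicate test. Set among random lists, the median of the members' own differences between the hairpins lay outside the middle 95% for p53 targets, Th17 and Tfh genes, cytokine receptors and JAK-STAT, and glycolysis and hypoxia, at percentiles of 100, 99.8, 0.07 and 0. It lay inside for pro-apoptotic genes and the stress response, at 94.8 and 97.495.

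A first pattern is the 66 genes at least 2-fold changed with both hairpins, some of which may reflect how reads shared between overlapping or near-identical genes were divided. Of them 36.4% had at least 50% of their 31-mers in another gene, against 8.91% on average and 24.2% at most in 10000 expression-matched sets. This is what shared reads would give. Whether it applies more to the read-through genes listed at 0 on 1 side was not tested. The 8 list members that were at least 2-fold lower with both hairpins hold mostly their own sequence. This argues against shared reads as the account of them as a group. The median shared 31-mer percent of these 8 was 0 and the highest was 35.7% (IFITM1), so some IFITM1 reads could be shared.

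A second pattern is the lower level of Th2, regulatory T cell, NF-kB target and chemokine genes, in lists that share some members. A bias from gene length or GC content between libraries is argued against, since after the trend on both was removed the highest percentile of the 4 lists with either hairpin was 0.02. Drift of the 1 scrambled line cannot be told apart from an effect of SATB1, because both hairpins were compared with that library. The knockdown of SATB1 remains open as the biological explanation that the design names.

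The last pattern is the higher level of both cell cycle lists. After removing the length and GC trend, which took up 1.94% of the variance of fold changes with shRNA 1 and 5.30% with shRNA 2, the lowest percentile of the 2 lists was 100, which argues against such a bias. Thinning the scrambled library to the lowest depth moved a list median by at most 0.0157, against a smallest median of 0.31. Thinned values were rescaled to the same expected FPKM, so this could show only the added counting error. Other effects of depth were not tested. Between the hairpin libraries the G2/M list was also shifted (-0.07), while the G1/S list was not (0.03). Drift of the 1 scrambled line, such as slower growth of that culture, again could not be separated with 1 scrambled library, and an effect of SATB1 stays open beside it.

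For the limma fit of both hairpins together, 3 splits of 1 library against 2 exist. The real split called 2 genes and the highest of the other splits called 1, and 1 split, the real one, gave as many. With 3 splits no share under 0.05 can be reached.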

How the results depend on the processing

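No paired analysis was possible because each group has 1 library. Of 35 alternatives for gene counts and the SATB1 level, 16 stayed within 1.5 times the reported count or within counting error and 19 moved. A count could not be labelled reversed, and the SATB1 log2 fold changes kept their sign, which the alternatives tried for them could not change. Of 214 for list medians 193 stayed and 21 moved. Of 136 for named genes 80 stayed and 56 moved, all 56 with a pseudocount of 0.1. In both kinds 0 were reversed. Centring on the median fold change could hardly move a result, since that median was 0.0009 with shRNA 1 and 0.0005 with shRNA 2. Centring gave 68 of the 80 named-gene results that stayed, 54 of the 193 list medians and 7 of the 16 counts and SATB1 levels. The named-gene results that stayed with a pseudocount of 0.1 numbered 12. With a pseudocount of 0.1, the genes past 2-fold numbered 327 with shRNA 1, 269 with shRNA 2, 121 with both and 236 between the hairpins, limma called 1, and the SATB1 log2 fold change with shRNA 1 was -0.69. With a mean of at least 5 FPKM they numbered 85, 72, 40 and 54, since fewer genes were counted. At 1.5-fold they numbered 584, 472, 205 and 417. Without genes that share sequence, an alternative chosen after seeing the data, 42 genes were past 2-fold with both hairpins and limma called 0, with 746 at an unadjusted p under 0.05. With no filter limma called 0, with 3133 at an unadjusted p under 0.05. Without trend or robust moderation it called 4, and at an adjusted p under 0.1 it called 6. A pseudocount of 0.1 can only enlarge fold changes, so the counts past 2-fold could only rise with it. Apart from this, the lower threshold, the sequence filter and the stricter expression filter, the cause was not tested. Depth limits low genes, and at 70.0 estimated fragments or fewer, as in the lowest 10% of expressed genes, counting error is widest.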

Other observations

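The genes in the next 2 paragraphs were named after their values were seen, and none passed limma over all genes. Genes in no fixed list that were at least 2-fold lower with both hairpins included AREG, STC1, RGS16, PTGER3, ZBTB32 and EEF1A2. AREG, which encodes the EGF receptor ligand amphiregulin, was 22.4 FPKM in the scrambled library, 6.48 FPKM with shRNA 1 and 5.45 FPKM with shRNA 2. STC1, which encodes the glycoprotein hormone stanniocalcin, was 23.7, 4.28 and 10.9 FPKM. RGS16, a brake on G protein signalling, was 8.69, 1.53 and 3.26 FPKM, and the prostaglandin E receptor gene PTGER3 was 6.43, 2.14 and 2.67 FPKM. ZBTB32, a zinc finger repressor of activated lymphocytes, was 16.2, 4.31 and 7.58 FPKM. EEF1A2, a translation elongation factor, was abundant in the scrambled library at 169 FPKM and 79.1 and 78.0 FPKM with the hairpins.

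Higher with both hairpins were MYD88, the adaptor of Toll-like receptors, at 3.50, 8.62 and 8.97 FPKM, and YWHAB, a 14-3-3 protein gene, at 12.5, 26.8 and 29.05 FPKM. The transcription factor gene ZEB1 was 3.27, 6.997 and 7.24 FPKM and the DNA repair gene UNG was 9.86, 19.4 and 20.6 FPKM, just short of 2-fold on the log2(FPKM + 1) scale. BCL2L11, which encodes the apoptosis activator BIM, was 0.132 FPKM in the scrambled library and 1.06 and 1.07 FPKM with the hairpins, a mean under the filter of 1 FPKM, so it entered no count. The surface marker genes CCR4 and IL2RA differed less, CCR4 at 274, 241 and 260 FPKM and IL2RA at 523, 425 and 480 FPKM.

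Because SATB1 organises chromatin, 1 hypothesis was co-ordinate change of neighbouring genes at these loci. Neighbours were taken among expressed genes with a symbol, so other genes may lie between them. Among 5675 such non-overlapping pairs within 100 kb, 4 pairs were both past 1.5-fold in the same direction with both hairpins. They were LIF with OSM on chromosome 22, and LTA with TNF, TNF with LTB, and LTB with NCR3 on chromosome 6. Shuffling the calls among genes 10000 times gave 1.10 pairs on average and 6 at most, and 262 shufflings gave at least as many as observed. By the rule set beforehand, a number at or below the bound counted against the hypothesis, and the observed 4 pairs equalled the bound. The predicted excess was therefore not met. With so few pairs, 3 of them from 1 locus, the test cannot exclude the hypothesis.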
